A study of Mus musculus with 5 samples.

How the data were processed

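RNA-seq was performed on 2 Krt6a+ and 3 WAP+ small pools of cells, isolated by flow sorting with an antibody to TVA, an avian virus receptor, from mammary lesions of MMTV-Wnt-1 mice on a mixed background. Per the labels' protocols, cDNA was made and amplified with a low-input full-length kit (SMART-Seq v4), libraries were made by Nextera tagmentation and paired reads were sequenced on an Illumina HiSeq. The kit does not mark the strand, so reads of overlapping antisense genes cannot be told apart. Amplification from few cells raises the scatter of low transcripts and can make a transcript drop out.

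Per the submitters' processing notes, TopHat and Cufflinks were used and the build was mm10; their versions, and the read filters, are not given in the sources used here. Each deposited table has 34535 RefSeq transcripts with 24347 symbols and gives, per the file headers, an FPKM value, the lower and upper 95% bounds of that FPKM, and a coverage. The FPKM was normalized by the authors for transcript length and mapped fragments. The deposited coverage is a read depth signal per base, proportional to FPKM within a library, and was used only to describe depth, at about 290000000 to 385000000 fragment bases per library. The status of every transcript was OK, yet Gapdh, Eno1, Rpl10 and Rpl11 were listed at 0 in 3 or more libraries, so an exact 0 can be a failed estimate. Genes at 0 in a whole population are given as listed at 0, with no fold. The low FPKM values were checked for whole-fragment steps: 31.7% to 34.2% of the values that implied at most 200 fragments lay within 0.02 of a whole number, so reads were not recovered and no count model was run. Read totals were estimated from the interval widths as Poisson error, which covers counting error only. No mitochondrially encoded gene was analysed here, so the mitochondrial share was not computed.

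Transcripts with the same symbol were summed. FPKM was divided by a factor per library, the median ratio to the geometric mean over the 5334 genes at FPKM 1 or more in all libraries; factors were 0.980 and 1.13 for the Krt6a+ libraries and 1.14, 0.909 and 0.873 for the WAP+ libraries. Genes with a deposited FPKM of 1 or more in at least 2 libraries were kept, 9682 in all. Values were log2(scaled FPKM + 1), so a fold change is on that scale and understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend; 3 residual and 4.87 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of means are SD over libraries of scaled FPKM, and errors of log2 differences are moderated standard errors. An exact two-sided permutation test of 2 against 3 libraries has 10 splits and cannot go below p = 0.1, so none is reported.

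Of 35 gene lists fixed before the data were examined, covering mammary lineages, pathways, other cell types and RNA quality, 29 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Of these, 8 lists passed camera with the preset correlation and 0 with an estimated correlation, where each of the 8 had an adjusted p of 0.399. The shared 0.399 arose in the adjustment over lists and does not rank them. Estimated correlations of the 8 lists ran from -0.131 (adipocyte) to 0.458 (ribosomal). That of the milk lipid list, 0.0040, was also below the preset, so a higher correlation alone did not remove the calls. By fry, only the milk lipid list of these 8 passed (adjusted p = 0.00386). The others did not, with fry adjusted p from 0.0626 (squamous, milk protein and adipocyte lists) to 0.0941 (luminal progenitor and secretory stress lists). Counts of members are given over all genes and adjusted over the list alone. The genes named, by a rule fixed before the data were examined, were Krt6a, Wap, Wnt1, Krt5, Krt14 and Krt8, then the 12 genes with the largest positive and the 12 with the largest negative difference past the threshold whose groups did not overlap, then up to 3 members per list with the largest moderated statistic. Small RNA, predicted and pseudogene models were left out of the second part. Further list members, and other genes, were named after their values were seen: in the list paragraphs to show both directions, and in the additional observations.

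The procedure was tested on simulated libraries with the real means and spreads. In the comparison of Krt6a+ with WAP+ libraries over 9682 genes, it recovered 11.6% of genes changed 4-fold, 64.5% of those changed 16-fold and 88.6% of those changed 64-fold, with 3.9% false calls, and gave 0 calls in runs with no change. Smaller changes were therefore mostly not detectable, and genes of low mean level were not among those changed. Simulated values were normal around the mean of each gene, with no drop-out to 0 and no failed estimates. In the data, 27 of the 67 genes past the threshold had a listed 0 in some library, so the share of false calls may not hold for them. Camera recovered 20 of 20 random lists of 15 genes shifted by 2 log2 units and called 2 of 180 unshifted lists. Genes were simulated independently, so this gives no rate of false calls for lists whose members vary together, such as the ribosomal list (estimated correlation 0.458).

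Alternatives fixed before the data were examined were no scaling, quantile normalization, other pseudocounts, filters and empirical Bayes settings, a replicate block, the highest row per symbol, no short or predicted models, an adjusted p under 0.1, an estimated correlation and leaving out each library. After the data were examined, genes above 0 in all libraries and the removal of a lowess trend with transcript length were added. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Coordinates are 1-based in mm10, from the deposited tables, with strands from a GENCODE annotation of the same build.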

Results

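The series compared 2 cell populations sorted from precancerous mammary lesions of MMTV-Wnt-1 mice, in which a Wnt-1 transgene driven in the mammary epithelium gives widespread hyperplasia. The labels describe the first population as keratin 6a positive (Krt6a+) precancerous stem cells and the second as cells positive for the whey acidic milk protein (WAP+), and the question was how their expression differed. There were 2 Krt6a+ libraries, numbered 2 and 3, and 3 WAP+ libraries, numbered 1 to 3, each of amplified cDNA from a small pool of cells. Levels were given as FPKM, fragments per kilobase of transcript scaled to the mapped fragments. The Krt6a+ libraries held 8112 and 8580 genes at FPKM 1 or more, and the WAP+ libraries 8900, 8420 and 8202. Read totals were not given. The widths of the 95% intervals around the FPKM values, read as counting error, corresponded to about 6710000 and 5230000 fragments in the Krt6a+ libraries and 4700000, 7210000 and 6190000 in the WAP+ libraries. Across the 5334 genes at FPKM 1 or more in all 5 libraries, Spearman's rho was 0.843 to 0.849 between WAP+ libraries, 0.743 between the Krt6a+ libraries and 0.696 to 0.761 between the populations, and Krt6a+ library 3 correlated more with WAP+ libraries 1 and 3 (0.761 and 0.750) than with Krt6a+ library 2. Nothing in the labels says that the libraries came from separate animals, so p-values measured only the spread between these samples, which may be technical. Both populations were sorted by TVA, and the labels do not say how TVA marked each. A difference between mice, lesions or sorts could therefore not be told apart from a difference between the populations.

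The genes that name the populations differed in the direction of the labels. Krt6a, a keratin of activated and stratified epithelia, had FPKM 1380 and 1133 in the Krt6a+ libraries and 168, 50.0 and 120 in the WAP+ libraries, so its transcript was present in both populations. Scaled means were 1206 ± 286 (SD, n = 2) and 113 ± 50.8 (SD, n = 3), and the log2 difference, Krt6a+ minus WAP+, was 3.50 ± 0.49 (SE), 11.3-fold on the log2(FPKM + 1) scale (limma, adjusted p = 0.0383). Wap, the milk protein gene, had FPKM 50.1, 126 and 13.9 in the WAP+ libraries and was listed at 0 in both Krt6a+ libraries (limma, adjusted p = 0.0448). In mm10 the Krt6a transcript NM_008476 lies on the minus strand of chromosome 15 from 101689928 to 101694305, and the Wap transcript NM_011709 on the minus strand of chromosome 11 from 6635483 to 6638649. The counting intervals of Krt6a were narrow, 1361 to 1399 in Krt6a+ library 2 and 46.1 to 53.9 in WAP+ library 2, which had the lowest value. Without Krt6a+ library 2 the adjusted p of Krt6a was 0.0573, and without WAP+ library 1, 2 or 3 it was 0.133, 0.146 and 0.165. For Wap the same refits gave 0.0573, 0.138, 0.202 and 0.102. Both calls were also lost with no filter (Krt6a 0.159, Wap 0.178), with no mean-variance trend (0.0776 and 0.0656) and with the highest row per symbol (0.0632 and 0.0683), that of Krt6a with a pseudocount of 0.1 (0.0619), and that of Wap with a pseudocount of 5 (0.0714), a replicate block (0.0674) and the length trend removed (0.0508).

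Among the other keratins named in the labels, Krt5, a basal keratin, was 16.2-fold higher in Krt6a+ libraries, with scaled FPKM of 387 ± 79.3 (SD, n = 2) against 24.7 ± 13.2 (SD, n = 3; limma, log2 difference 4.02 ± 0.49 SE, adjusted p = 0.0275). Its call was lost without WAP+ library 1, 2 or 3 (adjusted p = 0.133, 0.150 and 0.0557), with no filter (0.116), with no mean-variance trend (0.0553) and with a replicate block (0.0614). Krt14, the partner of Krt5, had FPKM 2284 and 2263 in Krt6a+ libraries and 936, 130 and 862 in WAP+ libraries, a difference that did not pass (limma, log2 2.14 ± 0.77 SE, adjusted p = 0.209). Krt8, a luminal keratin, had FPKM 1664, 1917 and 1681 in WAP+ libraries and 66.2 and 719 in Krt6a+ libraries. The last 2 values lay far apart, and Krt8 did not pass (limma, log2 -3.11 ± 0.81 SE, adjusted p = 0.117). Without Krt6a+ library 3, the library with more Krt8, the log2 difference was -4.71, and without library 2 it was -1.50. In these refits the spread between Krt6a+ libraries was not measured. Wnt1 itself had FPKM 7.91 and 6.94 in Krt6a+ and 10.3, 18.6 and 12.4 in WAP+ libraries and did not pass (limma, log2 -0.88 ± 0.56 SE, adjusted p = 0.466). The Wnt1 transcript NM_021279 of the endogenous gene spans 98789857 to 98793830 on the plus strand of chromosome 15. The FPKM of this model was not split between the endogenous gene and the transgene.

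**Figure D1:**
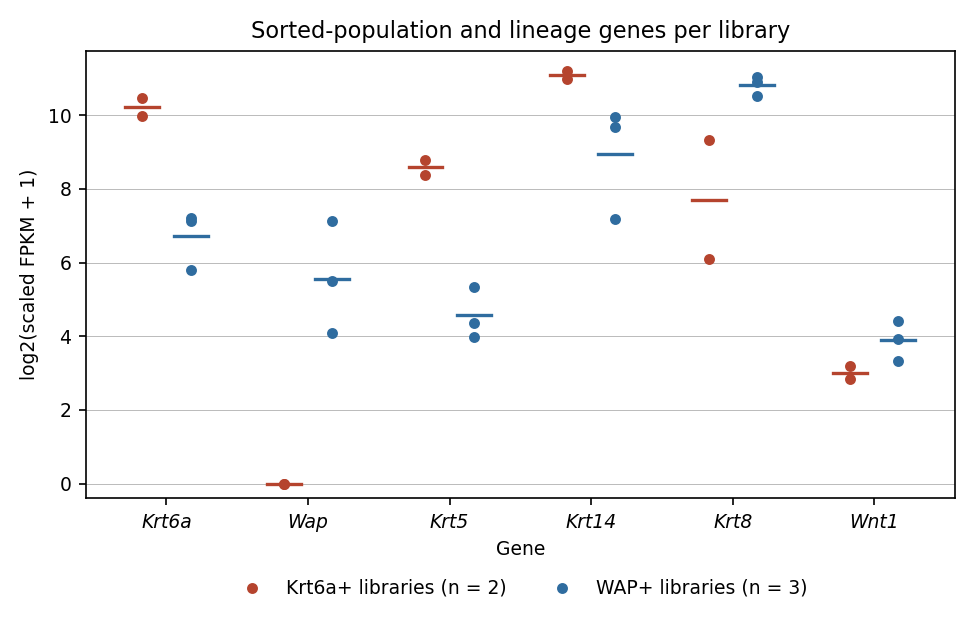
Each point is the level of a gene in 1 library, as log2(scaled FPKM + 1), with Krt6a+ libraries (n = 2) in red and WAP+ libraries (n = 3) in blue; horizontal bars are group means. Krt6a and Krt5 sit higher in both Krt6a+ libraries, Wap is at 0 in both, and the Krt8 values of the Krt6a+ libraries, FPKM 66.2 and 719, lie apart.

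Across 9682 tested genes, 25 were higher and 42 lower in Krt6a+ than in WAP+ libraries (limma, adjusted p under 0.05). At an unadjusted p under 0.05 there were 742 higher and 915 lower. All 67 genes past the adjusted threshold had groups that did not overlap, as did 34.8% of all tested genes, against 20% by chance for 2 against 3 libraries. Of these 67 genes, 15 were listed at 0 throughout 1 population, and an exact 0 can be a failed estimate, since the housekeeping genes Gapdh and Eno1 were listed at 0 in 3 and 5 libraries. Quantile normalization gave 39 higher and 39 lower, and removing a trend with transcript length gave 62 and 30. Without WAP+ library 1, 2 or 3 the higher genes numbered 2 each time and the lower genes 4, 3 and 4, and without Krt6a+ library 2 or 3 there were 10 and 56, and 44 and 103. Past the threshold without each WAP+ library in turn were Krt6b, Defb14, S100a8, Csf3 and Hp, and no other gene called with all 5 libraries.

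The 12 genes with the largest positive differences included the keratins Krt6b and Krt80. Krt6b, the paralog next to Krt6a on chromosome 15 (101676023 to 101680289), had scaled FPKM of 2421 ± 290 (SD, n = 2) in Krt6a+ and 1.10 ± 0.81 (SD, n = 3) in WAP+ libraries, a log2 difference of 10.25 ± 0.49 SE (limma, adjusted p = 0.000259). Krt6a and Krt6b are close paralogs, so how their shared reads were split is uncertain. Defb14, an antimicrobial beta-defensin, had FPKM 620 and 985 in Krt6a+ libraries and was listed at 0 in the WAP+ libraries (limma, adjusted p = 0.000259). S100g, a calcium-binding protein, with FPKM 69.4 and 355, and Calml3, a calmodulin-like protein of epithelia, with 29.4 and 14.9, were also listed at 0 in WAP+ libraries (limma, adjusted p = 0.0122 and 0.0448). Krt80, another epithelial keratin, was 104-fold higher, at 277 ± 189 (SD, n = 2) against 1.59 ± 1.45 (SD, n = 3), and Tppp3, a tubulin-binding protein, 45.4-fold (limma, adjusted p = 0.0122 and 0.0275). Dynap was at 3651 ± 3090 (SD, n = 2) against 148 ± 97.6 (SD, n = 3), with FPKM 5718 in Krt6a+ library 2 and 1653 in library 3. Tmprss11d, an epithelial serine protease, and Dusp10, a phosphatase of stress kinases, were 25.0-fold and 22.1-fold higher on the log2(FPKM + 1) scale (limma, adjusted p = 0.0478 and 0.0383). Plbd1 had FPKM 59.9 and 26.2 in Krt6a+ and 1.03, 1.33 and 0 in WAP+ libraries, Dhrs3, a retinaldehyde reductase, 29.4 and 18.4 against 0.18, 0 and 0, and Arg1, an arginase, 28.3 and 34.9 against 2.18, 0 and 0.70 (limma, adjusted p = 0.0478, 0.0424 and 0.0499). Without Krt6a+ library 2 or 3 the log2 difference was 5.95 or 7.44 for Krt80, 6.19 or 4.82 for Tppp3, 3.51 or 5.50 for Dynap and 3.43 or 5.87 for Tmprss11d, and without library 2 the last 2 genes did not pass (adjusted p = 0.0587 and 0.0749). Of the 12 genes, Krt6b and Defb14 passed without each WAP+ library.

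The 12 genes with the largest negative differences, which were higher in WAP+ libraries, included S100a8, Csf3, Hp, Spp1 and the milk genes Wap and Lalba. S100a8, a calcium-binding alarmin, had scaled FPKM of 4155 ± 1942 (SD, n = 3) in WAP+ and 3.52 ± 1.98 (SD, n = 2) in Krt6a+ libraries, 878-fold apart (limma, log2 -9.78 ± 0.54 SE, adjusted p = 0.000342). Csf3, the granulocyte colony-stimulating factor, was 141-fold higher in WAP+ libraries, at 245 ± 47.8 against 0.77 ± 0.55 (limma, log2 -7.14 ± 0.44 SE, adjusted p = 0.000573). Hp, the haemoglobin-binding acute phase protein haptoglobin, was 61.4-fold higher, at 675 ± 183 against 9.84 ± 2.44 (limma, adjusted p = 0.000954). Spp1, the secreted phosphoprotein osteopontin, was 90.2-fold higher, at 2741 ± 1374 against 32.1 ± 25.8 (limma, adjusted p = 0.0111). Chil1, a chitinase-like protein, had FPKM 373, 201 and 396 in WAP+ libraries and 5.14 and 0 in Krt6a+ libraries. Cel, a lipase of milk and pancreas, had FPKM 242, 165 and 182 in WAP+ and 0.13 and 13.4 in Krt6a+ libraries, and Apoc1, an apolipoprotein, 351, 560 and 435 against 4.57 and 33.2. Without Krt6a+ library 2 or 3 the log2 difference was -3.96 or -7.42 for Cel, -3.90 or -6.32 for Apoc1 and -5.60 or -7.38 for Spp1. Wfdc3, a protein with a WAP-type domain, had FPKM 110, 139 and 44.8 in WAP+ and 0 and 5.84 in Krt6a+ libraries. Lalba, the alpha-lactalbumin of lactose synthesis, had FPKM 32.0, 64.7 and 12.1, Cox7a1, a subunit of cytochrome c oxidase, 23.1, 80.7 and 44.0, and Sectm1a 60.4, 43.3 and 22.7 in WAP+ libraries, and these genes were listed at 0 in both Krt6a+ libraries. Of these lower genes, S100a8, Csf3 and Hp passed without each WAP+ library.

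**Figure D2:**
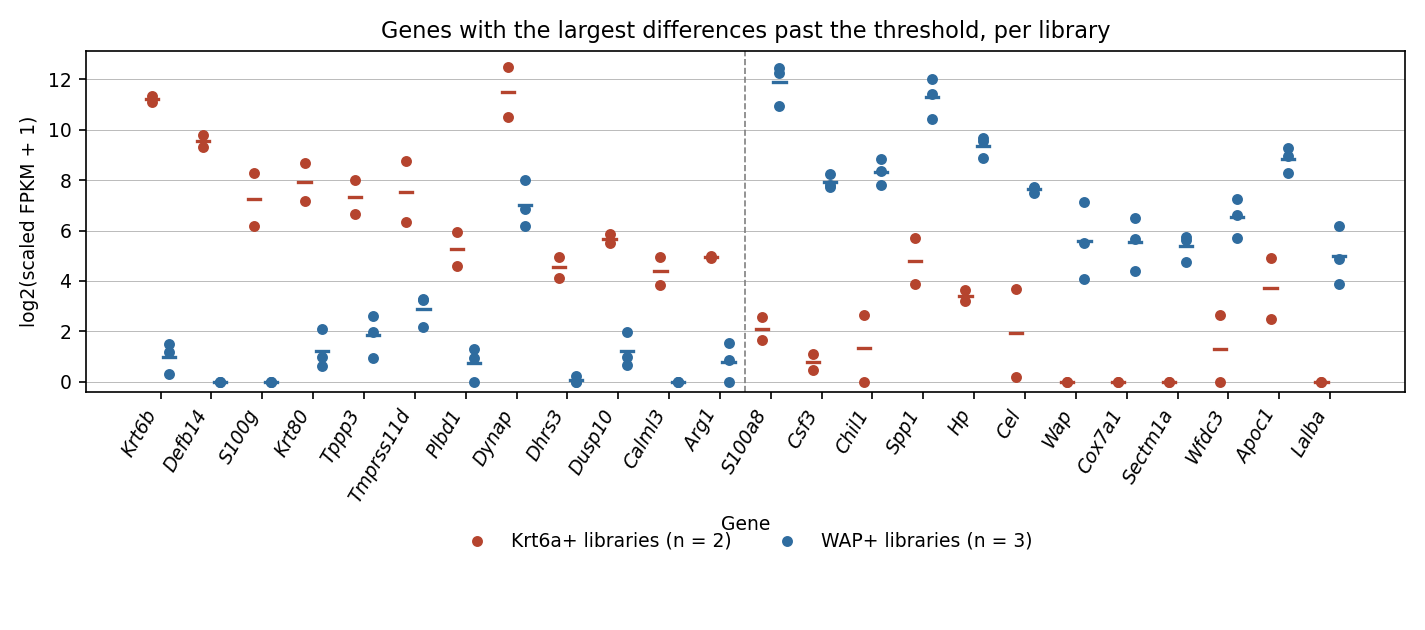
Points show log2(scaled FPKM + 1) per library for the 12 genes with the largest positive and the 12 with the largest negative difference past the threshold, divided by the dashed line, with Krt6a+ libraries in red, WAP+ libraries in blue and group means as bars. The groups do not overlap for any of the genes, and Defb14, S100g, Calml3, Wap, Cox7a1, Sectm1a and Lalba are at 0 in every library of 1 population.

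Genes of squamous and keratinised epithelium were higher as a list in Krt6a+ libraries. The median log2 difference of the 19 tested members was 2.47 (camera, adjusted p = 6.5e-09), and adjusted p = 0.399 with an estimated correlation. Over all genes 3 members passed, Krt6a, Krt6b and Calml3, and 16 did not. Adjusted over the list alone, 12 were higher and 0 lower, and Klk10 (log2 -0.73), Sfn (-0.38) and Serpinb5 (-0.26) had negative differences that did not pass. Among those 12 were Krt16, a keratin of activated epidermis (log2 2.70 ± 0.53 SE), Dsg3, a desmosomal cadherin (4.01 ± 0.73 SE), Tgm1, the transglutaminase that crosslinks the cornified envelope (1.99 ± 0.47 SE), and Sprr1a, a substrate of that crosslinking (2.47 ± 0.63 SE). Sprr1a reached FPKM 21990 in Krt6a+ library 2 and 6512 in library 3, against 3859, 1395 and 1458 in WAP+ libraries. Genes of differentiating epidermis varied in level. Krtdap had FPKM 214 and 42.4 in Krt6a+ and 26.8, 0 and 0 in WAP+ libraries, while Krt10 had 2.35 and 5.08 against 8.09, 0 and 0.15, and Lor 2.79 and 0 against 6.06, 0 and 0. Outside the list and named after their values were seen, Cnfn had FPKM 12322 and 4260 against 897, 483 and 184, Dmkn 4075 and 4737 against 1754, 866 and 1264, and Asprv1 4341 and 477 against 170, 63.3 and 106, and these did not pass over all genes (limma, adjusted p = 0.0520, 0.0758 and 0.0996). The list includes Krt6a, the gene for which the cells are named.

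Basal and myoepithelial genes went both ways. The median of 17 tested members was 0.56 (camera, adjusted p = 0.422), with 1 higher over all genes, Krt5. Adjusted over the list alone, 2 were higher, Krt5 and Trim29, and 2 lower, the contractile genes Acta2 and Tagln. Acta2 had FPKM 0.66 and 0.40 in Krt6a+ and 23.7, 25.2 and 8.35 in WAP+ libraries, and Tagln 0 and 2.65 against 24.0, 20.3 and 17.1, neither past the threshold over all genes (limma, adjusted p = 0.0547 and 0.0574). Trp63, the transcription factor of basal epithelia, had a log2 difference of 2.03 ± 0.76 SE that did not pass (limma, adjusted p = 0.228).

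Milk genes were lower as lists in Krt6a+ libraries, with members in both directions. The 15 tested milk protein and alveolar genes had a median log2 difference of -2.67 (camera, adjusted p = 5.0e-06), and adjusted p = 0.399 with an estimated correlation. Over all genes 4 members were lower, Spp1, Lalba, Wap and Cel, and 11 did not pass. Adjusted over the list alone 9 were lower and 1 higher, lactoferrin (Ltf, log2 2.16 ± 0.44 SE), Xdh (1.31) did not pass, and the median was -4.23 with a stricter filter. The caseins varied between WAP+ libraries: Csn3 had FPKM 5063, 2069 and 899, and Csn2 had 0, 246 and 1.03. The 19 milk lipid genes had a median of -1.37 (camera, adjusted p = 9.2e-05), and adjusted p = 0.399 with an estimated correlation. Plin2, a coat protein of lipid droplets, was 8.22-fold higher in WAP+ libraries, at 186 ± 55.7 (SD, n = 3) against 21.9 ± 8.67 (SD, n = 2; limma, adjusted p = 0.0447), and 18 members did not pass. Adjusted over the list alone 5 were lower and 0 higher, among them the desaturase Scd1 (log2 -2.36 ± 0.65 SE), and Me1 (0.54) had a positive difference that did not pass. The median of this list was -2.52 with a pseudocount of 0.1 and -0.63 with a pseudocount of 5. Adipocytes also express some of these genes, and adipocyte markers differed in the same direction (median of 4 members -1.99, camera, adjusted p = 0.0215, and adjusted p = 0.399 with an estimated correlation), with Fabp4 at FPKM 2188, 65.8 and 20.3 in WAP+ libraries and listed at 0 in Krt6a+ libraries. The prolactin and STAT5 signalling list, which acts upstream of milk genes, did not pass (median of 13 members -0.33, camera, adjusted p = 0.548).

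Luminal progenitor genes had a median log2 difference of -0.72 over 15 tested members (camera, adjusted p = 0.0268), and adjusted p = 0.399 with an estimated correlation. Over all genes 2 members were lower, Lcn2 and Cd14, and 13 did not pass. Lcn2, an iron-sequestering protein of innate defence, was 18.4-fold higher in WAP+ libraries, at 10440 ± 1283 (SD, n = 3) against 591 ± 256 (SD, n = 2), and Cd14, a receptor for bacterial lipopolysaccharide, 8.38-fold (limma, adjusted p = 0.00942 and 0.0275). Adjusted over the list alone 7 were lower, Lcn2, Cd14, Lbp (log2 -3.32), Rspo1 (-2.61), the transcription factor Sox10 (-2.52), Mfge8 (-1.87) and Lif (-1.67), and 1 was higher, Aldh1a3, a retinal dehydrogenase (1.92 ± 0.47 SE). The receptor Kit (1.01 ± 0.61 SE), the protease inhibitor Slpi (1.01 ± 0.46 SE) and the transcription factor Elf5 (-0.72 ± 0.53 SE) were among those that did not pass. The call was lost without Krt6a+ library 2 (median -0.84, adjusted p = 0.203), with a stricter filter (median -1.29, 0.116), with genes above 0 in all libraries (0.0718) and with a replicate block (median -1.23, 0.0530). The median was -1.61 without Krt6a+ library 3, -1.36 without WAP+ library 1 and -1.77 with a pseudocount of 0.1.

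The luminal epithelial list did not pass (16 members, median -0.27, camera, adjusted p = 0.155), although 7 members were lower and 2 higher adjusted over the list alone, and it passed without Krt6a+ library 3 (median -1.07, adjusted p = 0.0465). Its median was 0.03 with genes above 0 in all libraries. Krt18 had scaled FPKM of 3747 ± 268 (SD, n = 3) in WAP+ and 749 ± 549 (SD, n = 2) in Krt6a+ libraries (limma, log2 -2.54 ± 0.50 SE, adjusted p = 0.0607). Without Krt6a+ library 3 the log2 difference of Krt18 was -3.36 and without library 2 it was -1.71, with the spread between Krt6a+ libraries not measured. Krt18 passed with a stricter filter (limma, adjusted p = 0.0435), robust empirical Bayes (0.0487) and genes above 0 in all libraries (0.0246). Epithelial cytokines and acute phase genes also did not pass as a list (17 members, median -1.67, camera, adjusted p = 0.0815) and held members in both directions. Adjusted over the list alone 6 were lower, including Csf3, Lcn2 and Saa3 (log2 -4.54 ± 0.90 SE), and 4 higher, Il33 (3.64 ± 0.78 SE), Tnf, Tnfaip3 and Cxcl16. Saa1, an acute phase protein, had FPKM 221, 157 and 11.1 in WAP+ libraries and was listed at 0 in Krt6a+ libraries (limma, adjusted p = 0.0522). This list passed without Krt6a+ library 3 (0.0439), without WAP+ library 3 (0.0208) and with no scaling (0.0395). Its median was -0.86 without WAP+ library 1 (adjusted p = 0.415), -0.93 with a replicate block, -0.91 with the highest row per symbol, -0.72 with a stricter filter, -0.71 with a pseudocount of 5 and -0.64 with no filter, and it did not pass in these settings.

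Cell cycle genes were lower as a list in Krt6a+ libraries (16 members, median -1.02, camera, adjusted p = 0.00827), and adjusted p = 0.399 with an estimated correlation. No member passed by limma, over all genes or adjusted over the list alone, and levels were low: Cdk1, the mitotic kinase, had FPKM 0.19 and 0.62 in Krt6a+ and 4.24, 7.16 and 2.09 in WAP+ libraries, and Pcna, the highest member, reached 32.9. The call was lost with a stricter filter (adjusted p = 0.998), with genes above 0 in all libraries (0.194) and without Krt6a+ library 2 (0.112), and the median was -1.53 without Krt6a+ library 3. It was -2.42 and -0.37 with pseudocounts of 0.1 and 5, -0.66 with no filter, -0.24 with the stricter filter and -0.67 with genes above 0 in all libraries. Secretory stress genes were higher as a list (20 members, median 0.70, camera, adjusted p = 0.00278), and adjusted p = 0.399 with an estimated correlation. None passed over all genes, and 2 were higher adjusted over the list alone, Sdf2l1 and Creld2, which act in folding in the endoplasmic reticulum (log2 3.36 ± 0.63 and 1.74 ± 0.42 SE). The call was lost without Krt6a+ library 3 (median 0.30, adjusted p = 0.0845), and the median was 1.29 without library 2.

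Ribosomal protein genes were lower as a list in Krt6a+ libraries (22 members, median -1.41, camera, adjusted p = 1.9e-10), and adjusted p = 0.399 with an estimated correlation. No list member passed over all genes, and 17 were lower and 0 higher adjusted over the list alone. Rpl32 had scaled FPKM of 1194 ± 34.9 (SD, n = 2) in Krt6a+ and 4243 ± 862 (SD, n = 3) in WAP+ libraries (limma, adjusted p = 0.0594). Outside the list, Rplp2 (log2 -2.31 ± 0.35 SE) and Rps26 (-2.31 ± 0.38 SE), named after their values were seen, did pass over all genes (limma, adjusted p = 0.0448 and 0.0478), as did Rps16, with FPKM 20.3, 15.1 and 17.8 in WAP+ libraries and listed at 0 in both Krt6a+ libraries (adjusted p = 0.0383). Ribosomal protein genes took 4.06% and 3.57% of the summed FPKM in Krt6a+ libraries and 7.07%, 8.98% and 8.99% in WAP+ libraries. Transcript length moved with the populations: the median log2 difference was -0.88 for the 830 genes under 1000 bases and 0.21 for the 4248 genes over 3000 bases. After removal of the length trend the list's median was -0.53 (camera, adjusted p = 0.000114), and with quantile normalization it was -0.84.

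Genes induced early by stimulation or cell dissociation did not pass as a list (22 members, median 0.48, camera, adjusted p = 0.0596). Hspa1a, an inducible heat shock protein, was higher in Krt6a+ libraries (log2 3.17 ± 0.50 SE), at 98.9 ± 43.8 (SD, n = 2) against 9.79 ± 2.60 (SD, n = 3; limma, adjusted p = 0.0447), and its near-identical copy Hspa1b, with which it shares reads, did not pass (adjusted p = 0.172). The list passed without Krt6a+ library 2 (median 0.90, adjusted p = 3.7e-05) and had a median of -0.12 without library 3 (0.957) and 0.28 without WAP+ library 2 (0.207). It also passed without WAP+ library 3 (0.0464), with no scaling (0.0395), with quantile normalization (0.00145), with a replicate block (0.0266), with the highest row per symbol (0.0480) and with the length trend removed (0.0403). Nuclear retained RNAs did not pass (4 members, median 0.44, camera, adjusted p = 0.50). Neat1 had FPKM 364 and 273 in Krt6a+ and 154, 76.6 and 120 in WAP+ libraries.

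No list of stem cell or signalling genes passed the set test. Candidate mammary stem cell genes had a median of 0.01 over 16 members (camera, adjusted p = 0.546), and no member passed. Procr, a receptor used as a stem cell marker, had FPKM 0.12 and 7.64 in Krt6a+ and 227, 8.75 and 32.9 in WAP+ libraries, while Foxp1, a transcription factor, had 12.2 and 20.2 against 3.74, 2.05 and 5.04. Wnt and beta-catenin targets had a median of 0.23 over 12 members (adjusted p = 0.267). Nkd2, an inhibitor of Wnt signalling, had FPKM 44.6 and 23.2 against 3.13, 0.34 and 11.5, and Lgr5, a receptor for R-spondins, 2.32 and 2.49 against 0, 0 and 0.82. The Notch pathway (10 members, median 0.0011, adjusted p = 0.614), hormone-sensing luminal genes (7 members, 0.04, adjusted p = 0.850), ErbB and growth factor receptors (14 members, 0.48, adjusted p = 0.190) and mesenchymal transition genes (6 members, 0.32, adjusted p = 0.422) did not pass either. Neither did p53 targets and cell cycle arrest genes (17 members, 0.25, adjusted p = 0.383), where the kinase inhibitor Cdkn1a had a scaled FPKM of 373 ± 129 (SD, n = 2) in Krt6a+ and 126 ± 48.1 (SD, n = 3) in WAP+ libraries (limma, adjusted p = 0.138). Interferon response (11 members, 0.15, adjusted p = 0.872), apoptosis regulators (17 members, 0.13, adjusted p = 0.896) and hypoxia and glycolysis (17 members, -0.10, adjusted p = 0.896) did not pass. For apoptosis regulators the mean (-0.10), and for hypoxia the median, had the opposite sign to the direction of camera, which was up.

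**Figure D3:**
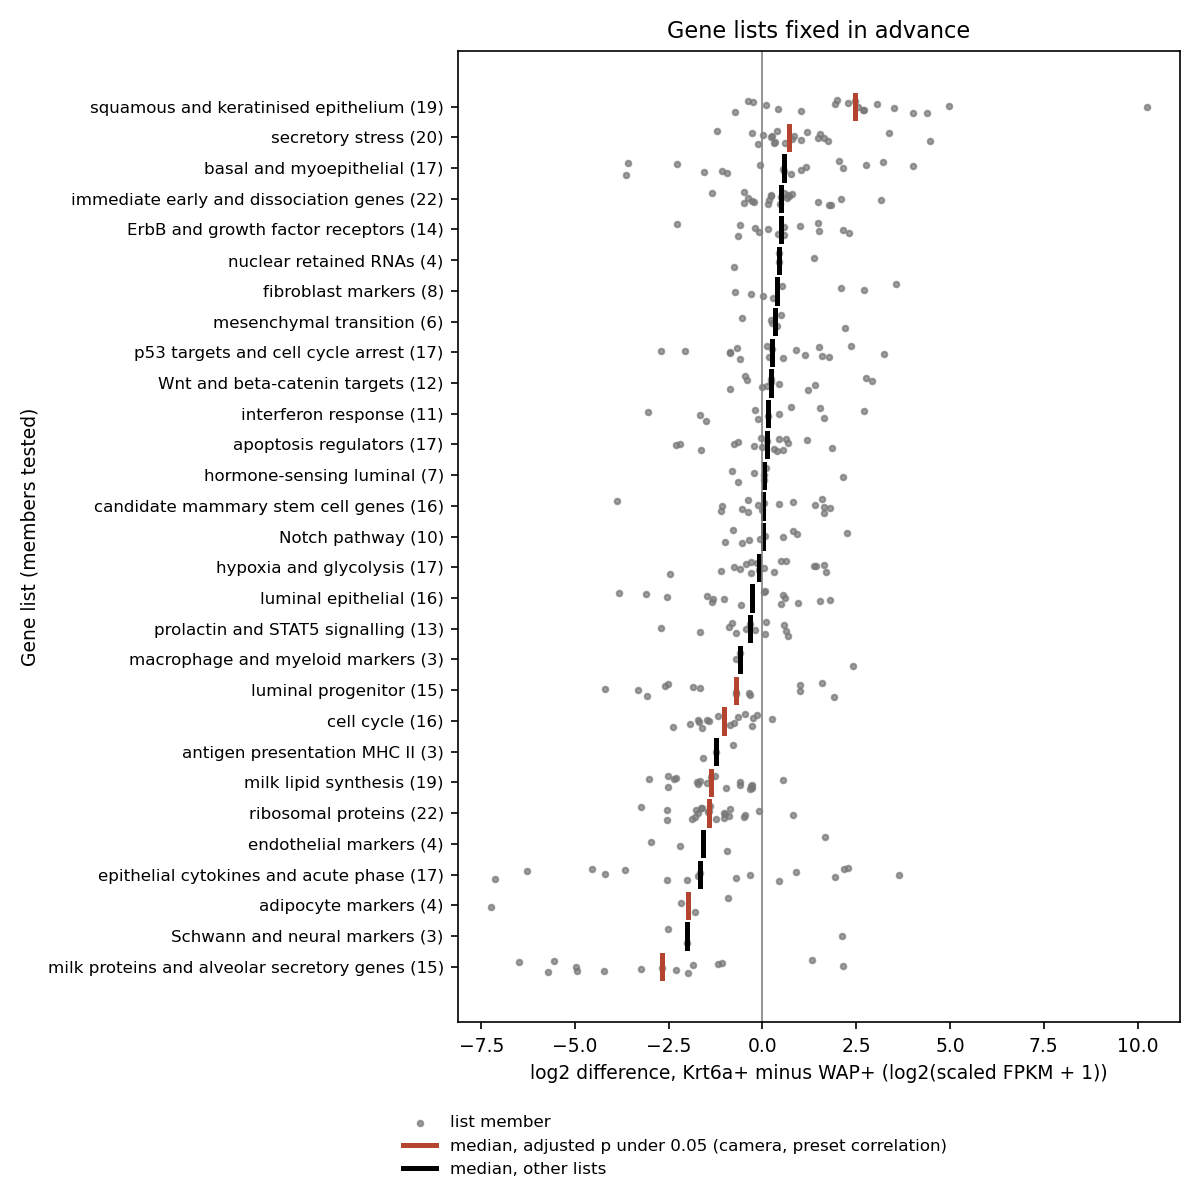
Each grey point is the log2 difference, Krt6a+ minus WAP+, of a tested member of a gene list, with the number of tested members beside each name; vertical bars are list medians, in red where the adjusted p of camera with a preset correlation was under 0.05. Squamous genes have the highest median, 2.47, and milk protein genes the lowest, -2.67.

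Markers of other cell types were tested as lists. The adipocyte list passed on 4 tested members (median -1.99, camera, adjusted p = 0.0215), and adjusted p = 0.399 with an estimated correlation. Among its members, Fabp4, a fatty acid carrier that endothelial cells also express, had FPKM 2188, 65.8 and 20.3 in WAP+ libraries and was listed at 0 in Krt6a+ libraries, Lipe, a lipase, had a scaled 5.30 ± 0.95 (SD, n = 3) against FPKM 0 and 1.01, and 7 of the 12 members were listed at 0 in all libraries. None passed over all genes, 2 were lower adjusted over the list alone, and the call was lost without Krt6a+ library 3 (median -3.08, adjusted p = 0.0576) and with a stricter filter (0.128). Its median was -3.74 and -0.89 with pseudocounts of 0.1 and 5. WAP+ library 1 also held endothelial transcripts, with FPKM 124 for Cldn5 and 112 for Esam against at most 6.76 and 3.64 in the other libraries, and the endothelial list did not pass (4 members, median -1.58, camera, adjusted p = 0.756). The fibroblast list did not pass (8 members, median 0.40, camera, adjusted p = 0.155), but it did without WAP+ library 3 (median 2.84, adjusted p = 0.0090) and with genes above 0 in all libraries (2.72, adjusted p = 0.00365). Its median was -0.09 with no filter (adjusted p = 0.918), 3.02 without Krt6a+ library 2 (adjusted p = 0.0985), 1.16 without Krt6a+ library 3 (0.218), 0.86 without WAP+ library 1 (0.192) and 0.09 without WAP+ library 2 (0.424). Dcn, a matrix proteoglycan, had FPKM 49.4 and 210 in Krt6a+ and 16.3, 8.60 and 67.0 in WAP+ libraries, and 2 fibroblast genes, Col6a1 and Postn, were higher adjusted over the list alone. Postn, a matrix protein, had FPKM 18.9 and 91.0 against 0.56, 6.74 and 2.04, and Mbp, a myelin protein of the Schwann and neural list, 27.4 and 30.5 against 9.11, 2.25 and 6.81. The other tested members of the Schwann and neural list, Sox10 (log2 -2.52) and Cnp (-2.02), went the other way. Adjusted over that list alone, 1 member was higher and 2 were lower. Macrophage and myeloid markers (3 members, median -0.61, adjusted p = 0.802, while mean and camera pointed up), Schwann and neural markers (3 members, -2.02, adjusted p = 0.546) and antigen presentation genes of MHC class II (3 members, -1.24, adjusted p = 0.155) did not pass. The remaining 6 lists had fewer than 3 tested members, and those of red cells, T and NK cells and B cells had 0. The highest values, red cells left aside, were FPKM 31.8 for the pericyte list (Ndufa4l2), 12.9 for pan-leukocyte markers (Arhgdib), 8.14 for skeletal muscle (Mylpf), 4.98 for T and NK cells (Lck) and 3.59 for B cells (Cd79a), and 8 of 10 pan-leukocyte markers were listed at 0 in all libraries.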

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

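The settings of genes above 0 in all libraries and of the length trend removed were chosen after seeing the data. Higher and lower genes in Krt6a+ libraries, 25 and 42, numbered 23 and 27 with no scaling, 39 and 39 with quantile normalization, 6 and 20 with a pseudocount of 0.1, 41 and 31 with a pseudocount of 5, 2 and 3 with no filter, 71 and 92 with a stricter filter of FPKM 5, 58 and 66 with robust empirical Bayes, 7 and 9 with no mean-variance trend, 8 and 16 with the highest row per symbol, 35 and 48 without short and predicted models, 145 and 180 at an adjusted p under 0.1, 76 and 91 with genes above 0 in all libraries and 62 and 30 with the length trend removed. Leaving out each library in turn gave 2 to 44 higher and 3 to 103 lower genes; where a population was left with 1 library, it was assumed to vary like the other. The cause of these changes was not tested. With a replicate block there were 15 and 19 genes, 7 and 13 of them among those called without it. Deviations of same-numbered libraries correlated at 0.05 and 0.00 across genes. With 2 Krt6a+ libraries their deviations mirror each other, so pairing of samples by number was not excluded. The fit without a block had been fixed before the data were examined. The number of lists past the set test, 8, was 5 with the stricter filter, 0 with an estimated correlation and 7 to 11 when each library was left out. These totals include lists newly past the test. Some of the 8 lists lost their call without each Krt6a+ library, and 7 of them kept it with a replicate block. None of the 30 named genes past the threshold, and none of the 8 lists, changed sign in the settings that tested them. With genes above 0 in all libraries 18 of these genes and 7 lists were tested, and without each Krt6a+ library 26 genes. The groups of these 30 genes did not overlap, so leaving out a library or changing the pseudocount or filter could hardly change their sign. For the genes, the unchanged signs are thus no support. The median log2 difference of all genes was -0.007, and 0.080 with no scaling.

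Results that changed direction were all short of the threshold with the main settings, and the cause was not tested; list directions are those of camera, with the median given. With no filter these were mesenchymal transition (-0.102), interferon response (-0.112) and macrophage markers (-0.459); with the stricter filter, stem cell genes (-0.131), Notch (-0.667), hypoxia (-0.138) and endothelial markers (-0.955); with the replicate block, apoptosis (0.045) and endothelial markers (0.046). With the highest row per symbol they were Socs2 (1.188), Fgfr1 (-0.960), hormone-sensing luminal genes (-0.621) and endothelial markers (-0.936); with genes above 0 in all libraries, hypoxia (-0.098); with the length trend removed, Tyrobp (0.539), apoptosis (0.255) and hypoxia (-0.054). Leaving out each library gave ranges of -2.741 to 1.436 for Areg, -2.038 to 0.425 for Prom1, -0.239 to 0.362 for hormone-sensing genes, -1.053 to 0.417 for stem cell genes, -0.074 to 0.623 for interferon response, -0.481 to 0.570 for hypoxia and -0.108 to 0.189 for apoptosis. The same refits gave medians of -0.152 to 0.74 for Notch, -0.04 to 0.676 for mesenchymal transition and -2.775 to -0.839 for endothelial markers. A test on raw counts was not run, since the values are FPKM.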

Other observations

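The genes of this paragraph passed the threshold outside the naming rule and were chosen after their values were seen. Higher in Krt6a+ libraries were Mxd1, a MYC antagonist, at a scaled FPKM of 108 ± 25.1 (SD, n = 2) against 6.09 ± 2.26 (SD, n = 3), Gsta4, a glutathione transferase, at 397 ± 158 against 38.6 ± 21.5, Nedd9, an adhesion scaffold, at 111 ± 15.3 against 14.6 ± 6.52, and Myd88, an adaptor of Toll-like receptors, at 70.2 ± 21.8 against 9.45 ± 1.30. Higher in WAP+ libraries were Wfdc18, a secreted protein with a WAP-type domain, at 16059 ± 4679 (SD, n = 3) against 1862 ± 1015 (SD, n = 2), Mgst1, a microsomal glutathione transferase, at 784 ± 342 against 71.3 ± 31.5, and Prdx4 and Fkbp11, which act in the endoplasmic reticulum, at 164 ± 17.3 against 14.3 ± 4.98 and 96.4 ± 22.3 against 7.56 ± 2.52. Prdx4 and Fkbp11 were thus lower in Krt6a+ libraries, where the secretory stress list was higher; neither is a member of that list.

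Metallothionein transcripts were among the most abundant in both populations: Mt1 had FPKM 13141 and 22669 in Krt6a+ and 29033, 29996 and 27791 in WAP+ libraries. Tsix was listed at 0 in Krt6a+ libraries and had FPKM 13.3, 13.0 and 19.7 in WAP+ libraries, while Xist, which it overlaps on the other strand, had 7.27 and 12.1 against 6.83, 7.18 and 4.68, and the libraries do not mark strand.

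Of the tests below, leaving out each WAP+ library, the medians of neutrophil and suprabasal genes above 0, with a bound of 1% of the median of the genes they were set against, and the median of ribosomal members above 0 were chosen after the values they rest on had been seen. S100a8, Csf3, Chil1, Lcn2 and Hp, picked after their values were seen, were higher in the 3 WAP+ libraries, while the cytokine and acute phase list did not pass (camera, adjusted p = 0.0815) and the defence genes Defb14, listed at 0 in WAP+ libraries, and Myd88 (log2 2.74) were higher in Krt6a+ libraries. Neutrophils in the WAP+ sorts are a candidate source of S100a8 and Lcn2, and the labels do not say how TVA marked the sorted cells. The median FPKM of 12 abundant neutrophil genes, 4 of which another list also holds, was 0 in each WAP+ library. Csf3r, Retnlg, Ngp and Camp were listed at 0, and the highest values were 52.8 (Srgn, library 1) and 10.6 (Alox5ap, library 3). In WAP+ libraries 1, 2 and 3, only 5, 3 and 3 of these neutrophil genes were above 0. Their medians of 2.68, 2.04 and 0.84 were in each library the value of Tyrobp, at most 0.315% of the median of the 5 genes. S100a9, the usual partner of S100a8, had 10.6, 9.81 and 116 where S100a8 had 2226, 4442 and 4912. These values argued against neutrophils as the main source of S100a8, though they rest on few genes. The difference of these 5 genes was not carried by 1 WAP+ library alone. Csf3 had FPKM 254, 193 and 262 against 0.37 and 1.30, and Lcn2 13525, 9151 and 8197 against 757 and 462. The log2 difference plus 2 standard errors nearest to 0 without 1 WAP+ library was -3.2 (Lcn2 without library 1, -4.13 ± 0.46 SE). The genes were picked with groups that did not overlap, so this refit could hardly have come out otherwise. It is no support and says nothing of other genes. Csf3, Hp and S100a8 passed the threshold without each WAP+ library in turn, and Chil1 and Lcn2 did not in every refit. A difference between the populations stays open and was not tested, and values listed at 0 can be failed estimates.

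Squamous genes were higher as a list in Krt6a+ libraries (camera, adjusted p = 6.5e-09, and adjusted p = 0.399 with an estimated correlation). Skin epidermis in the Krt6a+ sorts cannot be told apart from the pattern, and the labels do not say how TVA marked the sorted cells. The median FPKM of 7 measured suprabasal genes was 0 in both Krt6a+ libraries, with Krt1 listed at 0 and Krt10 at 2.35 and 5.08. Such zeros can be failed estimates, though, and genes of this set above 0 had medians of 2.79 and 23.7. Krtdap had 214 and 42.4, and Cnfn was among the 10 most abundant genes of both libraries. Of the 8 genes fixed for that test, 5 are also in a fixed gene list and 1 was not analysed here. The only genes of the set above 0 in Krt6a+ libraries, Krt10, Krtdap and Lor, are members of the squamous list itself. The medians above 0 were therefore not independent of the pattern. The 6 hair follicle genes had a median of 0 in each library. The highest were Tchh (12.3, Krt6a+ library 2) and Krt73 (29.6, library 3), against at most 1.06 in WAP+ libraries. The lowest median of the squamous list without 1 Krt6a+ library was 1.678, above the bound of 0.5 of its value with both, which argues against 1 library as the source. A difference between the populations stays open and was not tested.

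Ribosomal protein genes were lower as a list in Krt6a+ libraries (camera, adjusted p = 1.9e-10, and adjusted p = 0.399 with an estimated correlation), with none of the 22 members past the threshold over all genes, and short genes were lower too. The list's median was -1.414. That of 10000 random lists matched on length and level was -0.755 with a lower bound of -1.157, and 3 were as low. Genes of the random lists were drawn independently, whereas the ribosomal members varied together (estimated correlation 0.458). The bound may thus be too narrow, so transcript length as the whole explanation was not decided. Part of the difference did move with length, since the median was -0.533 with the trend removed. Failed estimates of genes with many copies cannot be told apart from the pattern: the 20 members above 0 in all libraries had a median of -1.441, but leaving out 2 of 22 members could have brought it to -1.327 at most, reads lost in part from the others were not measured, and Rps16, outside the list, was listed at 0 in both Krt6a+ libraries. A difference between the populations, in RNA quality or in amplification stays open and was not tested.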
